A study of Bos indicus and Bos indicus x Bos taurus and Bos taurus with 6 samples.

How the data were processed

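Whole-blood RNA of cows from 3 breeds was sequenced, with 2 biological replicates per breed. Total RNA was extracted with PrimeZOL reagent and an RNA integrity number above 7 was required, per the labels' protocols. The submitters' processing notes name FastQC 0.11.9, Trimmomatic 0.39, HISAT2 2.2.1, featureCounts 2.0.1 and DESeq2 1.38.0 with the bovine genome build ARS-UCD1.2. Their roles and settings, strandedness included, are not given in the sources used here. The deposited counts are whole-number read counts per gene, not normalised, for 21698 genes in each library, of which 3172 carry LOC symbols. The deposited FPKM values are those counts divided by a fixed gene length and by the total counted reads of the library. Over 2463 genes, the count divided by the FPKM deviated by at most 0.041% from the ratio of the library totals, so the FPKM values add no information on depth. Gene positions are given as in the deposited tables. There, 261 genes lie on a sequence that is not among the named chromosomes of ARS-UCD1.2, so positions are quoted as the authors' own and not tied to a build here. Of 16289 gene symbols shared with a reference gene table, 99.8% had the same chromosome name.

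Samples were grouped by the breed in their labels. Raw counts were tested in R 4.3.3 with edgeR 4.0.16. Library sizes were scaled by TMM, low-count genes were removed with filterByExpr while the 3 deiodinase genes were kept whenever they had a count, and a quasi-likelihood model with breed as its only term was fitted with robust estimation over all 6 libraries. F tests were made for Kedah-Kelantan against Holstein Friesian, Brangus against Holstein Friesian, Kedah-Kelantan against Brangus, and any breed difference. P-values were adjusted by Benjamini-Hochberg over the 13455 genes tested, and adjusted p under 0.05 was called. A positive log2 fold change means higher in the first breed named. The standard error (SE) is the log2 fold change divided by the square root of F. CPM values are counts scaled to the TMM-adjusted library size.

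The model, the comparisons, the 28 gene lists and the rule for naming genes were fixed before the data were examined. The lists covered thyroid, stress, immune and metabolic genes and markers of blood cell types. The 26 lists with at least 3 tested members were tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists within a comparison. Camera with an estimated correlation and fry were run beside it, and list members were also adjusted over the list alone. With an estimated correlation, camera tests on the 3 residual degrees of freedom. A lack of calls there need not come from correlation between genes. The deiodinase list with 1 tested member and the list of thyroid gland hormone synthesis with 2 were below this size. Genes were named by 4 rules. DIO1, DIO2 and DIO3 were always named. Of called genes with non-overlapping libraries and a mean log2 CPM of at least 1, up to 8 with the largest fold change were named per direction, or, where none passed, the 3 with the smallest p as values that did not pass. From each list that camera called or that held a called member, up to 3 members with the smallest p were named. HSPA1A, HSP90AA1, HSF1, THRA and THRB were named in each comparison. Of the genes these rules selected, 2 are not reported here. A gene outside these rules is said to have been chosen after its values were seen.

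Total counts ranged from 25275377 to 28668857 per library. A count of 0 was read as up to 3 counts, which is 0.0965 to 0.129 CPM depending on the library. Intervals for single counts are exact 95% Poisson intervals. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only, and the floor is too low for Brangus, where genes with 8 to 15 counts in one library often had 0 in the other. The common biological coefficient of variation was 0.43 with 3 residual degrees of freedom.

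The test was tried on simulated counts drawn with the fitted dispersions of these libraries, with 100 genes changed 4-fold and 100 changed 16-fold. Every breed was given the same dispersion per gene, and genes were drawn independently. The real breeds differed in spread, so the recoveries below may not hold for the real libraries. For Kedah-Kelantan against Holstein Friesian, edgeR recovered 40 at 4-fold and 89 at 16-fold and called 10 unchanged genes among 13144 tested. For Brangus against Holstein Friesian it recovered 51 and 86 and called 6 unchanged genes among 13161. For Kedah-Kelantan against Brangus it recovered 38 and 86 and called 10 unchanged genes among 13174. DESeq2 1.42.0 recovered 77, 75 and 73 at 4-fold in the same order and called 93, 82 and 79 unchanged genes.

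Alternatives to the normalization, the low-count filter, the test, the samples in the fit, the unit and the haemoglobin genes, a replicate block, and fits without each library in turn were also planned before the data were examined. A filter at a mean count of 50, a myeloid marker score as a covariate and the removal of a gene length trend were added after the data were seen. In a fit without 1 library, the lone library of its breed is assumed to vary like the others. No sample was left out of the tests reported, and DIO1 and DIO3, with 0 counts throughout, could not be tested.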

Results

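Gene expression was measured by RNA sequencing of whole blood taken from the jugular vein of cows under heat stress on 1 university farm in Malaysia. Kedah-Kelantan is an indigenous Bos indicus breed that the labels call heat-tolerant. Brangus is a composite breed of intermediate tolerance, and Holstein Friesian is a Bos taurus dairy breed called heat-vulnerable. Each breed had 2 biological replicates, so n = 2 per breed throughout. The design text speaks of 4 animals per breed, and how these relate to the 2 libraries per breed is not known here. All cows were non-pregnant, non-lactating adult females with a mean age of 4.5 ± 1.2 years and a mean weight of 450 ± 15 kg, according to the labels. All samples carry the same temperature-humidity index of 44.68, whose formula the labels do not give, so the comparisons are between breeds and not between heat loads. The title of the series asks how deiodinase genes, which activate or inactivate thyroid hormone, relate to thyroid metabolism and heat resilience in these breeds.

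Total counts were 27909440 and 28191440 for Kedah-Kelantan, 25275377 and 25465718 for Brangus, and 28668857 and 28102745 for Holstein Friesian, replicate 1 first. Genes with at least 1 count numbered 15178 and 15029, 13713 and 13260, and 14199 and 14683 in the same order. Over 9112 well-expressed genes, the median absolute log2 difference between the replicates of a breed was 0.13 for Kedah-Kelantan, 0.18 for Brangus and 0.48 for Holstein Friesian. Genes that differed over 2-fold between replicates numbered 12, 182 and 2003. Genes with 1 to 3 counts were fewer in Brangus, at 282 and 149, than in Kedah-Kelantan (1088 and 975) or Holstein Friesian (604 and 1014). The 2 Holstein Friesian libraries differed in blood cell markers. In replicate 2 minus replicate 1, the median log2 difference was 5.94 for eosinophil, basophil and mast cell markers, 3.62 for monocyte markers, 3.13 for neutrophil markers and 0.95 for platelet markers. It was -3.22 for B and plasma cell markers, -1.53 for gamma delta T cell markers, -0.98 for NK and cytotoxic lymphocyte markers, 0.39 for T cell markers and -0.24 for erythroid markers.

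**Figure D1:**
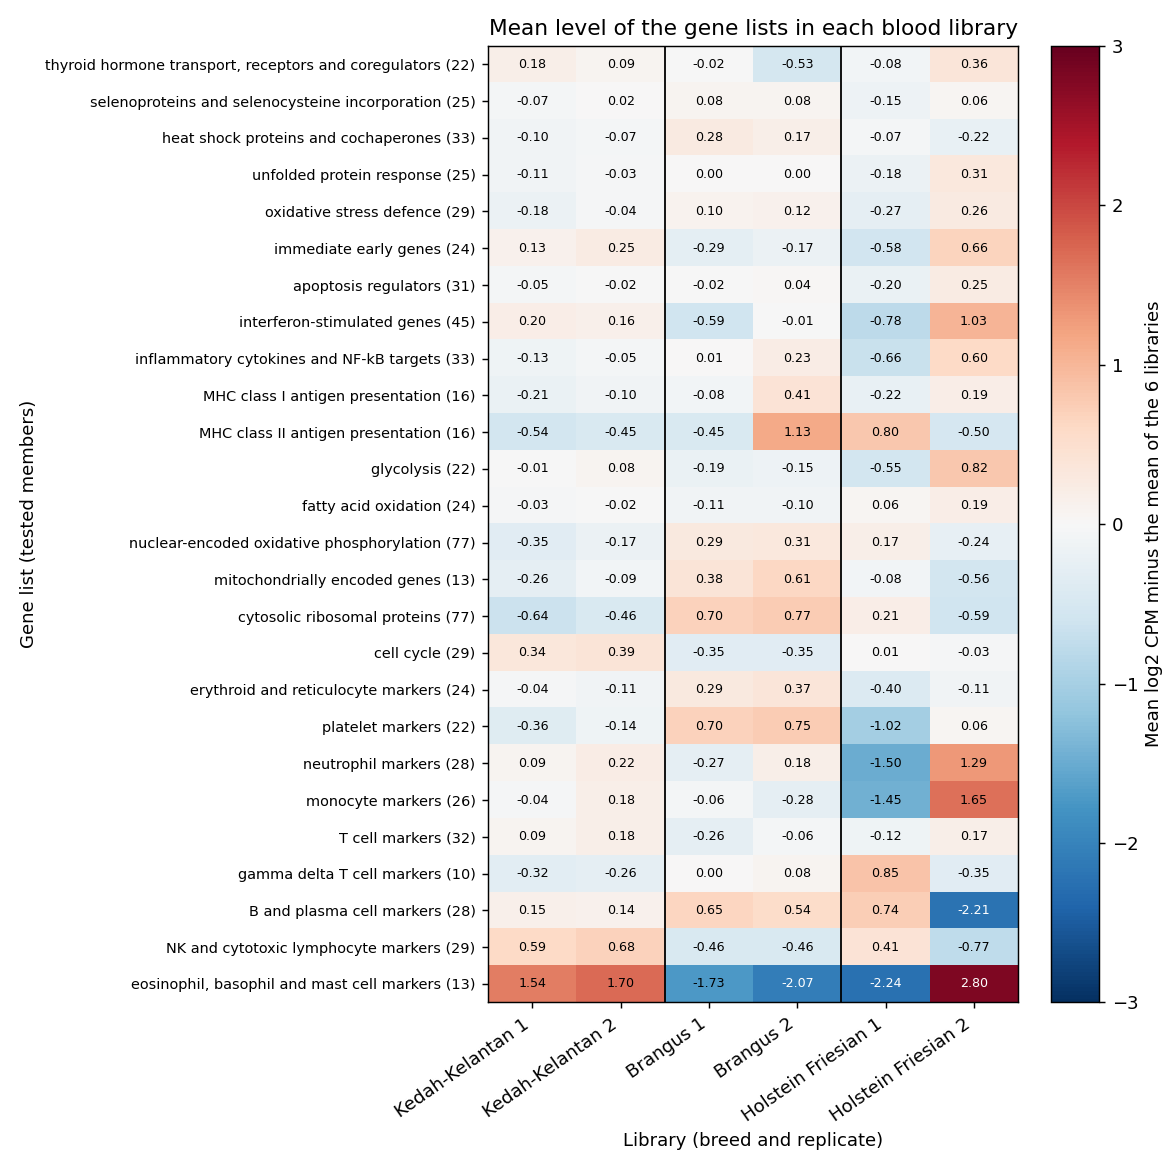
Heat map of the mean log2 CPM of each gene list in each library, minus the list's mean over the 6 libraries (columns are libraries by breed and replicate, and the value is printed in each cell). Eosinophil, basophil and mast cell markers stood at 1.54 and 1.70 in Kedah-Kelantan, -1.73 and -2.07 in Brangus, and -2.24 and 2.80 in Holstein Friesian.

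DIO1 and DIO3 were not detected in blood, and DIO2 was low in all libraries but 1. DIO1 (chromosome 3, 92310352 to 92330716, minus strand), whose enzyme converts thyroxine to active triiodothyronine mainly in liver and kidney, had 0 counts in all 6 libraries. DIO3 (chromosome 21, 66494396 to 66496497, plus strand), whose enzyme inactivates thyroid hormone, also had 0 counts in all 6. By counting error alone, a count of 0, read as up to 3 counts, allows up to 0.0965 CPM in Kedah-Kelantan replicate 1 and up to 0.129 CPM in Brangus replicate 2, the lowest and highest floors. The exact 95% Poisson interval of a count of 0 reaches 3.69 counts, somewhat above these floors. The Brangus limit is above its floor, since 37.5% of genes with 8 to 15 counts in one Brangus library had 0 in the other, against 4.3% in Kedah-Kelantan and 21.4% in Holstein Friesian, so low expression of DIO1 and DIO3 is not excluded. DIO2 (chromosome 10, 91490127 to 91504569, minus strand), whose enzyme activates thyroid hormone within tissues, had 4 and 11 counts in Kedah-Kelantan, 0 and 9 in Brangus, and 10 and 138 in Holstein Friesian. The 95% Poisson interval was 116 to 163 for Holstein Friesian replicate 2 and 4.8 to 18.4 for replicate 1. The other 4 libraries had intervals that reached no higher than 19.7. In CPM, DIO2 was 0.243 ± 0.162 (SD, n = 2) in Kedah-Kelantan, 0.193 ± 0.273 in Brangus and 2.79 ± 3.47 in Holstein Friesian.

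DIO2 did not pass edgeR's test in any comparison. Its log2 fold change was -3.50 (SE 1.91, adjusted p = 0.995) for Kedah-Kelantan against Holstein Friesian: deiodinase genes. It was -3.82 (SE 1.96, adjusted p = 0.663) for Brangus against Holstein Friesian: deiodinase genes, and 0.32 (SE 1.88, adjusted p = 0.964) for Kedah-Kelantan against Brangus: deiodinase genes. With DIO2 as the 1 tested member, the p adjusted over the list alone was 0.122, 0.105 and 0.87 by the same test. The lower values against Holstein Friesian rested on 1 library. Without Holstein Friesian replicate 2 they were -0.50 and -0.82. Without Holstein Friesian replicate 1, in which DIO2 was not high, they were -4.41 and -4.74, and the second then passed (adjusted p = 0.0356, over all alternatives 0.0356 to 0.967). The difference between Kedah-Kelantan and Brangus was -0.56 without Kedah-Kelantan replicate 2 and -0.67 without Brangus replicate 1. Without Brangus replicate 2 the Brangus count was 0, so that fit measured no fold for Brangus.

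**Figure D2:**
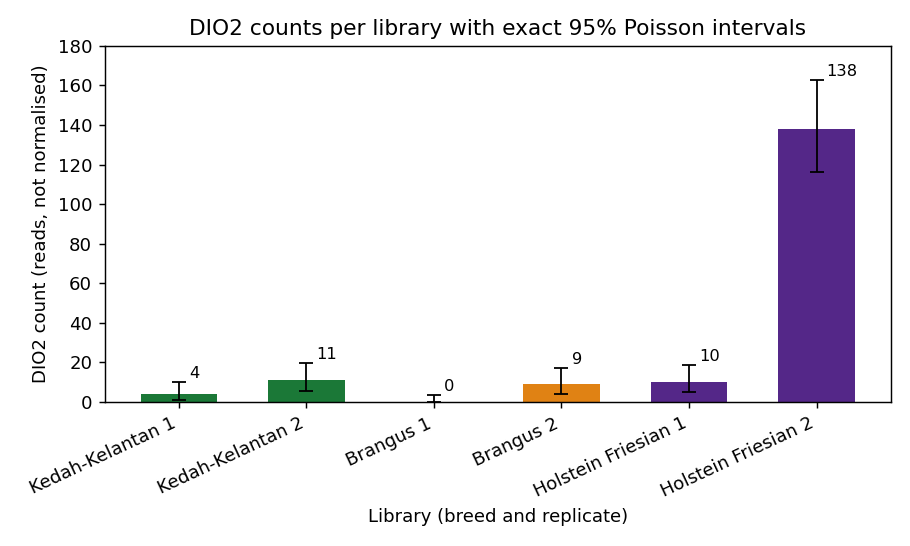
Bars show the DIO2 read count of each library, by breed and replicate, with exact 95% Poisson intervals. Holstein Friesian replicate 2 had 138 counts, and the other 5 libraries had 0 to 11.

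Neither thyroid hormone receptor gene passed in any comparison. THRA (chromosome 19, 40365895 to 40390931), a thyroid hormone receptor gene, was 33.2 ± 1.8 CPM in Kedah-Kelantan, 30.1 ± 2.87 in Brangus and 28.4 ± 8.21 in Holstein Friesian. Its log2 fold change was 0.23 (SE 0.25, adjusted p = 0.995) for Kedah-Kelantan against Holstein Friesian, 0.08 (SE 0.25) for Brangus against Holstein Friesian and 0.14 (SE 0.25) for Kedah-Kelantan against Brangus. The first 2 turned to -0.08 and -0.22 without Holstein Friesian replicate 2, the second to -0.05 without Brangus replicate 1, and the third to -0.10 with a gene length trend removed, where the median of all genes was also -0.10. THRB, the other receptor gene, was 1.21 ± 0.38, 0.599 ± 0.848 and 2.19 ± 2.06 CPM, with log2 fold changes of -0.85 (SE 1.67), -1.86 (SE 1.73) and 1.01 (SE 1.71). The first was 0.67 without Holstein Friesian replicate 2 and -1.59 without replicate 1, and the second was -0.34 without replicate 2. Brangus replicate 2 had a count of 0 for THRB, and without it THRB, Brangus against Holstein Friesian, was -0.91 and THRB, Kedah-Kelantan against Brangus, was 0.02. The list of thyroid hormone transport, receptors and coregulators had 22 tested members. Of these, 13 were higher and 9 lower in Kedah-Kelantan than in Holstein Friesian (median log2 fold change 0.07, camera adjusted p = 0.955), and the median was -0.07 without Kedah-Kelantan replicate 1 and -0.12 without Holstein Friesian replicate 1. In Brangus against Holstein Friesian 5 were higher and 17 lower (median -0.27, adjusted p = 0.0713), and in Kedah-Kelantan against Brangus 18 were higher and 4 lower (median 0.32, adjusted p = 0.0674), and neither passed. Of 25 selenoprotein genes, whose products include the deiodinases, the medians were 0.04, 0.09 and -0.11 (adjusted p = 0.658, 0.198 and 0.111), the first turning to -0.01 and -0.07 without Kedah-Kelantan replicates 1 and 2 and to -0.14 without Holstein Friesian replicate 2. Only 2 of 13 genes of thyroid hormone synthesis were expressed enough to test, with medians of -0.45, -0.13 and -0.32.

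The first comparison asked how the heat-tolerant breed differed from the heat-vulnerable one. In Kedah-Kelantan against Holstein Friesian, 1 of 13455 genes passed, with cytotoxic lymphocyte and cell cycle genes on the higher side as groups and ribosomal, nuclear-encoded oxidative phosphorylation, glycolysis, fatty acid oxidation, unfolded protein response, oxidative stress, gamma delta T cell and MHC class I genes on the lower side. With an estimated correlation no list passed (smallest adjusted p = 0.359). The gene that passed was LOC539009 (chromosome 8, 71366038 to 71367420), described as ras-related GTP-binding protein A, whose relatives signal amino acid supply to mTORC1. It had 1288 and 1462 counts in Kedah-Kelantan, 1072 and 932 in Brangus, and 5 and 9 in Holstein Friesian. In CPM this was 44.5 ± 4.29, 43.0 ± 4.14 and 0.255 ± 0.123 (SD, n = 2), a log2 fold change of 7.44 (SE 0.39, edgeR adjusted p = 0.0455). RRAGA, described as Ras related GTP binding A, went the other way, at 34.37 and 40.56 CPM in Kedah-Kelantan, 42.22 and 38.06 in Brangus, and 89.19 and 87.97 in Holstein Friesian, so the split of reads between LOC539009 and RRAGA is uncertain. The sequences of the 2 genes were not compared here. The call of LOC539009 was lost without any 1 of the Kedah-Kelantan or Brangus libraries, with a replicate block, with only the 2 breeds in the fit and with a filter at a mean count of 50, while in these fits LOC539009, Kedah-Kelantan against Holstein Friesian, kept a log2 fold change of 7.33 to 7.53. The call held with DESeq2 (7.44, adjusted p = 1.17e-52), without Holstein Friesian replicate 1 (7.00, adjusted p = 7.18e-05) and without replicate 2 (7.97, adjusted p = 4.41e-05).

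**Figure D3:**
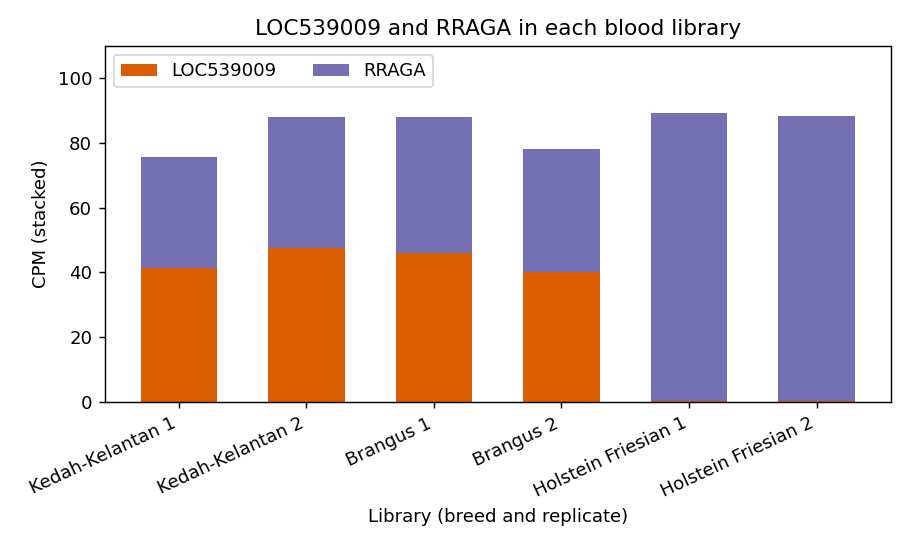
Stacked bars show the CPM of LOC539009 and of RRAGA in each library, by breed and replicate. LOC539009 was 0.17 and 0.34 CPM in Holstein Friesian and 40.04 to 47.51 CPM in the other 4 libraries, while RRAGA was 87.97 and 89.19 CPM in Holstein Friesian and 34.37 to 42.22 CPM in the others.

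Among genes that did not pass, the lower ones with the smallest p in Kedah-Kelantan were TTLL1 (a tubulin glutamylase component), LOC101903126 (an interferon-induced very large GTPase 1 gene) and LOC789829 (sorting nexin-5-like). TTLL1 was 5.65 ± 1.07 CPM in Kedah-Kelantan and 33.4 ± 3.56 in Holstein Friesian (log2 fold change -2.56, SE 0.27). LOC101903126 was 44.3 ± 5.09 and 259 ± 74.6 CPM (-2.55, SE 0.28), and LOC789829 was 0.679 ± 0.041 and 8.91 ± 0.408 CPM (-3.71, SE 0.43). All 3 had an adjusted p of 0.501. DESeq2 called each of them, as well as CCL5, KLRK1, NCR1, TPI1, PDK1 and SLC25A20 below, and 131 genes in all (65 higher, 66 lower). In the simulation, DESeq2 called 93, 82 and 79 unchanged genes in the 3 comparisons, against 10, 6 and 10 with edgeR. Its calls, here and below, are therefore less certain than its adjusted p implies. edgeR had 543 genes at an unadjusted p under 0.05, fewer than the 673 that chance gives. Without Holstein Friesian replicate 1 edgeR called 2464 genes and without replicate 2 it called 1669, of which 67 higher and 64 lower were shared and 674 were called in opposite directions.

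NK and cytotoxic lymphocyte markers were higher in Kedah-Kelantan, with 23 of 29 members higher (median log2 fold change 0.41, camera adjusted p = 5.38e-07; adjusted p = 0.732 with an estimated correlation). CCL5 (chromosome 19, 14509140 to 14515888), a chemokine of cytotoxic cells, was 211 ± 32.8 CPM against 60.1 ± 17.2 (1.81, SE 0.26, adjusted p = 0.58). KLRK1 (chromosome 5, 99603137 to 99613786), the activating receptor NKG2D, was 32.8 ± 2.86 against 7.74 ± 1.96 (2.08, SE 0.30, adjusted p = 0.58), and NCR1, an NK cell receptor, was 40.8 ± 3.54 against 13.8 ± 5.43 (1.57, SE 0.34, adjusted p = 0.995). Adjusted over the list alone, 4 members passed, and DESeq2 called 3 members higher and 1 lower. The list median was -0.03 without Holstein Friesian replicate 2 and 1.21 without replicate 1, and the list's level was 0.41 in replicate 1 and -0.77 in replicate 2. Cell cycle genes were higher in 27 of 29 cases (median 0.34, adjusted p = 2.8e-05; adjusted p = 0.359 with an estimated correlation), among them TOP2A (0.56, SE 0.19), CENPF (0.58, SE 0.22) and MCM2 (0.54, SE 0.21), genes of chromosome segregation and DNA replication. Without Holstein Friesian replicate 2 that median was 0.20 and the call was lost.

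Ribosomal protein genes and nuclear-encoded genes of energy metabolism were lower in Kedah-Kelantan as groups. All 77 cytosolic ribosomal protein genes were lower (median -0.40, adjusted p = 1.21e-12; adjusted p = 0.94 with an estimated correlation), among them RPL23A (-1.28, SE 0.38), RPL3 (-0.61, SE 0.19) and RPSA (-0.52, SE 0.19). Ribosomal protein genes have processed pseudogenes, so their read assignment is uncertain. Nuclear-encoded oxidative phosphorylation genes were lower in 72 of 77 cases (median -0.27, adjusted p = 2.44e-07; adjusted p = 0.94 with an estimated correlation), with NDUFB10 (-0.47, SE 0.18), ATP5PD (-0.55, SE 0.22) and NDUFV2 (-0.45, SE 0.19) as members with the smallest p. The ribosomal median was 0.05 without Holstein Friesian replicate 1 and -0.76 without replicate 2, and the oxidative phosphorylation median was 0, without a call, without replicate 1. The list levels in replicates 1 and 2 were 0.21 and -0.59 for ribosomal and 0.17 and -0.24 for oxidative phosphorylation genes. RPL23A was -0.65 and ATP5PD -0.31 without replicate 1. Glycolysis genes were lower in 20 of 22 cases (median -0.39, adjusted p = 0.0243; adjusted p = 0.948 with an estimated correlation). TPI1, triosephosphate isomerase, was 104 ± 7.95 against 188 ± 6.65 CPM (-0.86, SE 0.16) and GAPDH was lower (-0.51, SE 0.23), while PDK1, whose product inhibits pyruvate dehydrogenase, was higher (0.72, SE 0.16). The glycolysis median was 0.29, a call on the higher side, without Holstein Friesian replicate 2 and -0.85 without replicate 1, the list level was -0.55 and 0.82 in replicates 1 and 2, and GAPDH was -0.27 without replicate 2. It was -0.37 without Kedah-Kelantan replicate 1 and -0.43 with a gene length trend removed, neither a call. Fatty acid oxidation genes were lower in 18 of 24 cases (median -0.25, adjusted p = 0.0395; adjusted p = 0.732 with an estimated correlation). SLC25A20 (-0.87, SE 0.20) and ACSL5 (-0.44, SE 0.16) were lower and HADH higher (0.85, SE 0.20), and the call was lost without any 1 of the Kedah-Kelantan or Holstein Friesian libraries (medians -0.27 to -0.17).

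Lists of the unfolded protein response, oxidative stress defence and MHC class I were lower as well. The unfolded protein response was lower in 19 of 25 genes (median -0.16, adjusted p = 0.0243; adjusted p = 0.94 with an estimated correlation), with PDIA6 (-0.48, SE 0.17), PDIA3 (-0.47, SE 0.18) and TRIB3 (-0.45, SE 0.23). Oxidative stress defence was lower in 22 of 29 (median -0.19, adjusted p = 0.0247; adjusted p = 0.94 with an estimated correlation), with the peroxiredoxin PRDX5 (-0.60, SE 0.19), the glutaredoxin GLRX (-0.59, SE 0.22) and the sulfiredoxin SRXN1 (-0.52, SE 0.23). MHC class I antigen presentation was lower in 14 of 16 (median -0.34, adjusted p = 0.00685; adjusted p = 0.94 with an estimated correlation), with the class I gene BOLA (-0.68, SE 0.23) and the immunoproteasome gene PSMB8 (-0.55, SE 0.18) lower and the nonclassical BOLA-NC1 higher (1.01, SE 0.35). None of these 3 lists kept its call without Holstein Friesian replicate 2 (medians 0.04, -0.10 and -0.03) or without Kedah-Kelantan replicate 1 (medians -0.13, -0.06 and -0.33). TRIB3 was -0.15 without Holstein Friesian replicate 1 and -0.74 without replicate 2, and SRXN1 was -0.29 without replicate 2. The oxidative stress call was also lost with a gene length trend removed (-0.26). Gamma delta T cell markers were lower in 10 of 10 genes (median -0.75, adjusted p = 0.0107; adjusted p = 0.862 with an estimated correlation), including WC1-12 (-1.45), CD163L1 (-1.25) and TARP (-1.84, SE 1.05), and the median was 0.19 without Holstein Friesian replicate 1, whose list level was 0.85 against -0.35 in replicate 2. Without it WC1-12 was -0.74, CD163L1 -0.51 and TARP 0.84. That call was also lost with the length trend removed (-0.96). None of the members named from these lists passed on its own (adjusted p = 0.947 for TPI1, 0.58 for CCL5 and KLRK1, and 0.995 for the others).

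The other lists did not pass in this comparison. Heat shock proteins and cochaperones, the main heat response genes, had 14 of 33 members higher (median -0.03, adjusted p = 0.676, and 0.11 without Holstein Friesian replicate 1). HSPA1A (chromosome 23, 27520317 to 27522790), the inducible HSP70, was 159 ± 10.5 CPM in Kedah-Kelantan, 168 ± 5.77 in Brangus and 160 ± 68.4 in Holstein Friesian, with a log2 fold change of -0.01 (SE 0.31). It was -0.39 without Holstein Friesian replicate 1, 0.47 without replicate 2, and, for HSPA1A, Kedah-Kelantan against Holstein Friesian, 0.22 in a limma-trend fit of log2(FPKM + 1), where the median of all genes was 0.12. It was 0.06 without Kedah-Kelantan replicate 1. HSP90AA1 was -0.24 (SE 0.16), and HSF1, the master regulator of the heat response, was 0.14 (SE 0.18), and HSF1, Kedah-Kelantan against Holstein Friesian, was 0.26 and 0 without Kedah-Kelantan replicates 1 and 2 and 0.07 without Holstein Friesian replicate 2. Medians and adjusted p were -0.28 and 0.71 for immediate early genes, -0.17 and 0.24 for apoptosis regulators, -0.33 and 0.284 for interferon-stimulated genes, -0.37 and 0.126 for inflammatory cytokines and NF-kB targets, and -0.20 and 0.266 for MHC class II. They were 0.11 and 0.241 for mitochondrially encoded genes, -0.04 and 0.955 for erythroid markers, -0.05 and 0.955 for platelet markers, -0.86 and 0.468 for neutrophil markers, -0.80 and 0.134 for monocyte markers, 0 and 0.571 for T cell markers, 0.21 and 0.126 for B and plasma cell markers, and -0.41 and 0.45 for eosinophil, basophil and mast cell markers. Many of these depended on 1 Holstein Friesian library. Without replicate 1 the medians of the immediate early, interferon-stimulated, inflammatory, neutrophil, monocyte and eosinophil lists were -0.71, -0.90, -0.78, -1.76, -1.66 and -1.46, all called lower, and without replicate 2 they were 0.50, 0.70, 0.42, 1.34, 1.65 and 4.38, all called higher. B and plasma cell markers were 2.67 without replicate 1 and -0.67 without replicate 2, also called both ways. The apoptosis (-0.25) and mitochondrially encoded (0.33) lists were called without replicate 1 and turned to 0.20 and -0.16 without replicate 2, and the mitochondrially encoded median was -0.02 without Kedah-Kelantan replicate 2. MHC class II (-0.53) and platelet (0.75) lists were called without Holstein Friesian replicate 2, and MHC class II was 0.76, without a call, without replicate 1. The platelet median was also above 0 without Kedah-Kelantan replicate 1 (0.08) or Brangus replicate 2 (0.11), and the erythroid median without Kedah-Kelantan replicate 2 (0.11) or either Holstein Friesian library (0.11 and 0.05). Camera placed the eosinophil and platelet lists on the higher side and the selenoprotein list on the lower side, opposite to their medians, and the means of the thyroid transport and erythroid lists (-0.11 and 0.1) were opposite to their medians. Adjusted over the list alone, 1 platelet and 1 inflammatory gene passed, and none in the lists other than these and the NK list.

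The second comparison asked how the composite breed differed from Holstein Friesian. In Brangus against Holstein Friesian, platelet, ribosomal, mitochondrial and heat shock genes were higher as groups at the preset correlation, while with an estimated correlation no list passed (smallest adjusted p = 0.453). LOC539009 was the 1 gene that passed (7.39, SE 0.38, adjusted p = 0.0468). Its call was lost with median-of-ratios scaling, with a replicate block, with only the 2 breeds in the fit, with a filter at a mean count of 50 and without any 1 of the Kedah-Kelantan or Brangus libraries, while LOC539009, Brangus against Holstein Friesian, kept a log2 fold change of 7.25 to 7.44. It held with DESeq2 (7.39, adjusted p = 7.15e-52), without Holstein Friesian replicate 1 (6.95, adjusted p = 1.36e-05) and without replicate 2 (7.92, adjusted p = 6.3e-05). Platelet markers were higher in 16 of 22 cases (median log2 fold change 1.49, camera adjusted p = 8.57e-11; adjusted p = 0.453 with an estimated correlation), and 7 passed adjusted over the list alone. PPBP (chromosome 6, 88915411 to 88917013), a platelet chemokine, was 130 ± 40.8 CPM in Brangus and 18.3 ± 1.13 in Holstein Friesian (2.82, SE 0.27, adjusted p = 0.302). PF4 (chromosome 6, 88924248 to 88925219), platelet factor 4, was 698 ± 14.9 against 267 ± 12.9 (1.39, SE 0.20, adjusted p = 0.452) and TUBB1, the platelet beta-tubulin, was 169 ± 2.12 against 66.0 ± 13.2 (1.35, SE 0.19, adjusted p = 0.452). Without Holstein Friesian replicate 1 the list median was 0.95 and its call was lost (adjusted p = 0.071), and 8 members were called higher both without replicate 1 and without replicate 2.

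All 77 ribosomal protein genes were higher in Brangus (median 0.86, adjusted p = 1.6e-37; adjusted p = 0.574 with an estimated correlation), with 65 at an unadjusted p under 0.05 and 0 passing adjusted over the list alone by edgeR. DESeq2 called 4 of them. RPL3 was 2761 ± 52.3 CPM against 1484 ± 172 (0.90, SE 0.19), RPL28 0.82 (SE 0.18) and RPS19 0.93 (SE 0.24). With a gene length trend removed the ribosomal median was 0.49, and the list level was 0.21 and -0.59 in the 2 Holstein Friesian libraries. All 13 mitochondrially encoded genes were higher (median 0.70, adjusted p = 5.89e-10; adjusted p = 0.563 with an estimated correlation), and 9 passed adjusted over the list alone. They included ND1 at 3266 ± 529 against 1660 ± 40.2 CPM (0.98, SE 0.20), ND3 (1.34, SE 0.31) and ATP6 (0.86, SE 0.22). The list level was -0.08 and -0.56 in Holstein Friesian replicates 1 and 2. ND1, ND3 and ATP6 were 0.95, 1.72 and 0.97 without replicate 1, and 0.96, 0.99 and 0.71 without replicate 2. Nuclear-encoded oxidative phosphorylation genes were higher in 73 of 77 cases (median 0.28, adjusted p = 2.34e-07; adjusted p = 0.641 with an estimated correlation), with ATP5PF (0.56, SE 0.20), COX6B1 (0.46, SE 0.17) and COX7C (0.85, SE 0.32). With the length trend removed that median was -0.01 and COX6B1, Brangus against Holstein Friesian, was -0.02. The median was 0.10, without a call, without Holstein Friesian replicate 2, where ATP5PF was 0.32 and COX7C 0.43, and COX7C was 1.37 without replicate 1. Heat shock proteins and cochaperones were higher in 29 of 33 cases (median 0.29, adjusted p = 0.000403; adjusted p = 0.453 with an estimated correlation). HSP90AB1 was 1425 ± 90.9 against 899 ± 182 CPM (0.67, SE 0.21), the constitutive chaperone HSPA8 2139 ± 118 against 1460 ± 124 (0.55, SE 0.18), and the mitochondrial cochaperonin HSPE1 85.9 ± 6.51 against 50.7 ± 14 (0.76, SE 0.25), each with an adjusted p of 0.645. Without Holstein Friesian replicate 2 HSP90AB1 was 0.43 and HSPE1 0.46, and HSPE1 was 1.07 without replicate 1. Single members were called higher in 9 cases and lower in 1 without replicate 1, and in 0 and 1 without replicate 2. HSPA1A was 0.08 (SE 0.31), and HSPA1A, Brangus against Holstein Friesian, was -0.31 without Holstein Friesian replicate 1, 0.56 without replicate 2 and 0 without Brangus replicate 2. HSP90AA1 was 0.39 (SE 0.16, adjusted p = 0.656) and HSF1 0.21 (SE 0.18), and HSF1, Brangus against Holstein Friesian, was 0.11 without Brangus replicate 1.

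Interferon-stimulated genes were lower in Brangus in 42 of 45 cases (median -0.61, adjusted p = 0.000271; adjusted p = 0.641 with an estimated correlation). IFITM1, an antiviral membrane protein gene, was 323 ± 73.7 against 673 ± 3.71 CPM (-1.06, SE 0.22), OAS1X -2.39 (SE 0.80) and TRIM25 -0.98 (SE 0.36). The list level was -0.78 and 1.03 in the 2 Holstein Friesian libraries, the median was 0.21, a call on the higher side, without replicate 2, and it was -0.43, without a call, without Brangus replicate 1. OAS1X was -0.94 and TRIM25 -0.54 without Holstein Friesian replicate 2. Eosinophil, basophil and mast cell markers were lower in 12 of 13 cases (median -2.58, adjusted p = 0.00176; adjusted p = 0.641 with an estimated correlation). ALOX15, a lipoxygenase of eosinophils, had 3 and 0 counts in Brangus and 7 and 16142 in Holstein Friesian, CEBPE, a granulocyte transcription factor gene, had 0 and 0 against 4 and 959, and the interleukin-5 receptor gene IL5RA was 16 ± 4.09 against 95.6 ± 98.4 CPM. The eosinophil median was 0.19 without replicate 2, the library with the high counts, and -3.97 without replicate 1. B and plasma cell markers were higher in 25 of 28 cases (median 0.62, adjusted p = 0.000194; adjusted p = 0.641 with an estimated correlation), with CR2 at 1.05 (SE 0.60), SWAP70 at 0.44 (SE 0.31) and PRDM1 at -0.67 (SE 0.33), and the median was -0.15 without replicate 2 and 3.16 without replicate 1. In the same order CR2 was 0.40 and 2.15, SWAP70 0.02 and 0.95 and PRDM1 -0.15 and -1.08, and CR2, Brangus against Holstein Friesian, was 0.52 without Brangus replicate 2. Cell cycle genes were lower in 22 of 29 cases (median -0.44, adjusted p = 0.00162; adjusted p = 0.453 with an estimated correlation), including MKI67 (-1.01, SE 0.29), TOP2A (-0.63, SE 0.19) and AURKB (-1.31, SE 0.42), a call lost without replicate 1 (median -0.48). Erythroid markers were higher in 17 of 24 cases (median 0.45, adjusted p = 0.0327; adjusted p = 0.453 with an estimated correlation), with the beta-globin gene HBB (1.73, SE 0.46) and TRIM58 (1.97, SE 0.56) higher and the haem synthesis gene FECH lower (-0.83, SE 0.19), and this call was also lost without replicate 1 (median 0.61), with the length trend removed (0.35), with a mean count of at least 50 (0.23) and with the myeloid marker score as a covariate (0.54).

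The lower genes with the smallest p in Brangus were GZMB, granzyme B, at 21.3 ± 0.809 against 79.2 ± 3.61 CPM (-1.90, SE 0.20, adjusted p = 0.34), MTARC2 at 6.05 ± 0.107 against 22.6 ± 1.59 (-1.90, SE 0.25, adjusted p = 0.452) and LOC101903126 (-2.04, SE 0.28, adjusted p = 0.452). None passed with edgeR, and DESeq2 called all 3 among 313 genes (148 higher, 165 lower). edgeR had 1025 genes at an unadjusted p under 0.05. It called 4395 genes without Holstein Friesian replicate 1 and 849 without replicate 2, with 112 higher and 62 lower shared and 409 in opposite directions. Medians and adjusted p of the other lists were -0.17 and 0.433 for the unfolded protein response, 0.17 and 0.168 for oxidative stress defence, -0.31 and 0.0817 for immediate early genes, -0.11 and 0.738 for apoptosis regulators, and -0.09 and 0.558 for inflammatory genes. They were -0.02 and 0.711 for MHC class I, 0.33 and 0.0509 for MHC class II, -0.26 and 0.0509 for glycolysis, -0.05 and 0.381 for fatty acid oxidation, -0.44 and 0.711 for neutrophil, -0.70 and 0.113 for monocyte, -0.27 and 0.0817 for T cell, -0.45 and 0.254 for gamma delta T cell, and -0.18 and 0.0509 for NK and cytotoxic lymphocyte markers. Here too the Holstein Friesian libraries disagreed. The immediate early, glycolysis, neutrophil and monocyte medians were -0.76, -0.64, -1.30 and -1.55 without replicate 1, all called lower, and 0.34, 0.15, 1.89 and 1.5 without replicate 2, all called higher. Without replicate 2 the inflammatory (0.75) and oxidative stress (0.27) lists were called higher and the NK (-0.73) and gamma delta T cell (-1.11) lists lower, the last 2 being 0.10 and 0.36 without replicate 1. MHC class II was called without replicate 1 (1.25) or Brangus replicate 1 (0.19), and T cell markers without Brangus replicate 2 (-0.50). The apoptosis, unfolded protein response and MHC class I medians turned to 0.05, 0.07 and 0.23 without Holstein Friesian replicate 2, and the last to 0.04 without Brangus replicate 1. The tests of the inflammatory and MHC class I lists pointed higher, against their medians, and the selenoprotein mean (-0.12) had the opposite sign to its median. Adjusted over the list alone, 1 apoptosis and 1 NK gene passed, and none in the lists other than these, the platelet and the mitochondrially encoded.

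The third comparison set the heat-tolerant breed against the composite one, and here the replicates differed over 2-fold in fewer genes than in Holstein Friesian (12 and 182 against 2003). The Brangus libraries stood apart in their low counts, with 282 and 149 genes at 1 to 3 counts against 1088 and 975, and 37.5% of genes with 8 to 15 counts in one library at 0 in the other against 4.3%, so values near 0 in Brangus are uncertain. In Kedah-Kelantan against Brangus, cytotoxic lymphocyte, cell cycle and eosinophil genes were higher and platelet, ribosomal, mitochondrial and heat shock genes lower as groups, at the preset correlation. With an estimated correlation no list passed (smallest adjusted p = 0.172), and no single gene passed edgeR's main test, which fitted all 6 libraries. PF4 was 121 ± 23.6 CPM in Kedah-Kelantan and 698 ± 14.9 in Brangus (-2.53, SE 0.21). MYL9, a smooth muscle and platelet myosin light chain gene, was 68.4 ± 12 against 299 ± 11.9 (-2.13, SE 0.22), and FXYD4, an ion transport regulator gene, was 50 ± 6.13 against 320 ± 0.243 (-2.67, SE 0.26). On the higher side, ADGRG1, an adhesion receptor of cytotoxic lymphocytes, was 82.6 ± 4.46 against 21.5 ± 4.35 (1.94, SE 0.26), CCL5 was 211 ± 32.8 against 56.6 ± 0.407 (1.9, SE 0.26), and IMPDH1, an enzyme of guanine nucleotide synthesis, was 43.2 ± 2.95 against 17.6 ± 1.56 (1.29, SE 0.18). All 6 had an adjusted p of 0.337, the smallest in this comparison.

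edgeR called 0 genes in this comparison with 1564 at an unadjusted p under 0.05, and DESeq2 called 672 (302 higher, 370 lower). With only Kedah-Kelantan and Brangus in the fit, so that the spread did not include the Holstein Friesian libraries, edgeR called 2537 genes (1195 higher, 1342 lower). It called 2448 without Holstein Friesian replicate 1 and 2458 without replicate 2, and 1086 higher and 1265 lower genes were the same in both, with 0 in opposite directions. The number of edgeR calls thus depended on which libraries set the spread. With all 6 libraries in the fit, calls also depended on the method, at 672 with DESeq2. With a myeloid marker score as a covariate, edgeR called 1998. Neutrophil marker levels were -1.5 and 1.29 in Holstein Friesian and -0.27 to 0.22 in the other libraries. Monocyte levels were -1.45 and 1.65 against -0.28 to 0.18. This covariate can therefore take the difference between the Holstein Friesian libraries out of the spread, much as leaving out 1 of them does.

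Platelet markers were lower in Kedah-Kelantan in 18 of 22 cases (median -1.35, adjusted p = 4.32e-09; adjusted p = 0.38 with an estimated correlation). TUBB1 (-1.67, SE 0.20) and PPBP (-1.95, SE 0.26) followed PF4, 7 members passed adjusted over the list alone, and 11 were called lower and 1 higher with only the 2 breeds in the fit. Erythroid markers were lower in 19 of 24 cases (median -0.68, adjusted p = 0.0281; adjusted p = 0.38 with an estimated correlation), with HBB at 162 ± 26.1 against 536 ± 139 CPM (-1.72, SE 0.46) and TRIM58 lower (-1.37, SE 0.55) but FECH higher (1.20, SE 0.19). The erythroid call was lost without Brangus replicate 2, without either Holstein Friesian library (medians -0.60, -0.72 and -0.73), with only the 2 breeds in the fit, with the myeloid marker score (-0.64) and with a gene length trend removed (-0.39). NK and cytotoxic lymphocyte markers were higher in 25 of 29 cases (median 0.82, adjusted p = 1.39e-08; adjusted p = 0.38 with an estimated correlation). KLRK1 was 2.12 (SE 0.30) and GZMB 1.09 (SE 0.19), 7 members passed adjusted over the list alone, and 13 were called higher and 1 lower with only the 2 breeds. Cell cycle genes were higher in 27 of 29 cases (median 0.81, adjusted p = 1.39e-08; adjusted p = 0.172 with an estimated correlation). TOP2A was 54.6 ± 6.76 against 23.9 ± 2.63 CPM (1.19, SE 0.19), the proliferation marker MKI67 was 100 ± 27.3 against 30.9 ± 6.14 (1.70, SE 0.30) and MCM2 was 1.17 (SE 0.21), and 9 members passed adjusted over the list alone. T cell markers were higher in 23 of 32 cases (median 0.28, adjusted p = 0.039; adjusted p = 0.538 with an estimated correlation), with CTLA4 (1.91, SE 0.57) and BCL11B (0.68, SE 0.22), a call lost without Kedah-Kelantan replicate 2 or Brangus replicate 1 (medians 0.19 and 0.16). B and plasma cell markers were lower in 23 of 28 cases (median -0.47, adjusted p = 0.0281; adjusted p = 0.699 with an estimated correlation), with FCER2 (-0.82, SE 0.20), CD72 (-1.17, SE 0.61) and SWAP70 (-0.69, SE 0.31), a call lost without Brangus replicate 1 (median -0.54) and with a gene length trend removed (-0.57).

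Eosinophil, basophil and mast cell markers were higher in 11 of 13 cases (median 2.57, adjusted p = 0.000102; adjusted p = 0.509 with an estimated correlation). ALOX15 (chromosome 19, 26697233 to 26705814) had 5550 and 5639 counts in Kedah-Kelantan and 3 and 0 in Brangus. CEBPE had 353 and 497 against 0 and 0, which gives no firm bound on the fold, since a count of 0 in Brangus does not limit expression to 3 counts. IL5RA was 95.1 ± 7.94 against 16 ± 4.09 CPM (2.57, SE 0.86). With only the 2 breeds in the fit, 9 members were called higher.

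All 77 ribosomal protein genes were lower in Kedah-Kelantan (median -1.26, adjusted p = 3.9e-57; adjusted p = 0.38 with an estimated correlation), and 76 passed adjusted over the list alone. RPL3 was 974 ± 99.5 against 2761 ± 52.3 CPM (-1.50, SE 0.20, adjusted p = 0.337), RPL23A 461 ± 25.7 against 2428 ± 360 (-2.40, SE 0.39) and RPSA 1723 ± 123 against 3761 ± 1.94 (-1.13, SE 0.19). These genes are short (median length 636 bases against 3050 for all genes), and with a gene length trend removed the median was -0.86. Over 12175 genes, the log2 fold change of this comparison correlated with gene length (Spearman 0.33). The medians of other lists of short genes may carry this trend too. Nuclear-encoded oxidative phosphorylation genes were lower in 75 of 77 cases (median -0.55, adjusted p = 2.55e-17; adjusted p = 0.473 with an estimated correlation), with NDUFB10 (-0.90, SE 0.18), COX4I1 (-1.13, SE 0.24) and ATP5PD (-0.96, SE 0.22). Of these, 37 had an unadjusted p under 0.05, 0 passed adjusted over the list alone by edgeR, and DESeq2 called 8. All 13 mitochondrially encoded genes were lower (median -0.65, adjusted p = 2.08e-06; adjusted p = 0.473 with an estimated correlation), among them ND3 (-1.23, SE 0.31), ATP8 (-1.40, SE 0.36) and ND1 (-0.69, SE 0.20).

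Heat shock proteins and cochaperones were lower in Kedah-Kelantan than in Brangus in 29 of 33 cases (median -0.27, camera adjusted p = 0.000363, and 0.38 with an estimated correlation). The list level was -0.10 and -0.07 in Kedah-Kelantan, 0.28 and 0.17 in Brangus, and -0.07 and -0.22 in Holstein Friesian. Brangus thus stood above both other breeds, while Kedah-Kelantan against Holstein Friesian did not pass (median -0.03, camera adjusted p = 0.676). HSP90AA1 (chromosome 21, 66939612 to 66944979), the inducible cytosolic HSP90, was 703 ± 4.69 against 1083 ± 46.5 CPM (-0.62, SE 0.17), AHSA1, which activates HSP90, was 69.0 ± 1.26 against 108 ± 1.72 (-0.65, SE 0.15) and HSPE1 was 44.0 ± 5.77 against 85.9 ± 6.51 (-0.96, SE 0.25), each with an adjusted p of 0.353. With only the 2 breeds in the fit, 10 members were called lower and 0 higher. HSPA1A (-0.09, SE 0.31) and HSF1 (-0.07, SE 0.18) differed by less than their error, and HSPA1A, Kedah-Kelantan against Brangus, and HSF1, Kedah-Kelantan against Brangus, were both 0.17 in a limma-trend fit of log2(FPKM + 1), where the median of all genes was 0.19. HSF1 was also 0.06 without Kedah-Kelantan replicate 1. Oxidative stress defence genes were lower in 24 of 29 cases (median -0.39, adjusted p = 0.00324; adjusted p = 0.473 with an estimated correlation), with PRDX5 (-0.88, SE 0.19), SRXN1 (-1.01, SE 0.23) and PRDX6 (-0.71, SE 0.18), a call lost with the length trend removed.

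MHC class I genes were lower in 11 of 16 cases (median -0.21, adjusted p = 0.0214; adjusted p = 0.59 with an estimated correlation), with BOLA at 1018 ± 123 against 2914 ± 631 CPM (-1.52, SE 0.24), B2M (-0.80, SE 0.21) and PSMB8 (-0.78, SE 0.18). Bovine class I genes are near-identical copies, so their read assignment is uncertain, and the call was lost without Kedah-Kelantan replicate 1 or Brangus replicate 2 (medians -0.11 and -0.06). MHC class II genes were lower in 15 of 16 cases (median -0.57, adjusted p = 0.00335; adjusted p = 0.493 with an estimated correlation), a call lost with the length trend removed. BOLA-DQB had 2 and 0 counts in Kedah-Kelantan and 6 and 6548 in Brangus, BOLA-DQA5 had 2 and 5 against 3 and 3538, and IFI30, a lysosomal thiol reductase gene, was -0.65 (SE 0.22). Counts of another tested entry, BLA-DQB, are not given here, so BOLA-DQB may not hold all reads of DQB. Interferon-stimulated genes were higher in Kedah-Kelantan in 36 of 45 cases (median 0.53, adjusted p = 0.0114; adjusted p = 0.699 with an estimated correlation), with IFITM1 (0.68, SE 0.22), OAS1X (2.27, SE 0.79) and USP18 (0.92, SE 0.33), a call lost without Brangus replicate 1 (median 0.31). Medians and adjusted p of the other lists were 0 and 0.334 for the unfolded protein response, 0.12 and 0.279 for immediate early genes, -0.05 and 0.46 for apoptosis regulators, -0.33 and 0.0674 for inflammatory genes, -0.09 and 0.912 for glycolysis, and -0.09 and 0.521 for fatty acid oxidation. They were -0.15 and 0.881 for neutrophil, 0.21 and 0.596 for monocyte and -0.32 and 0.329 for gamma delta T cell markers. Inflammatory genes were called lower without Kedah-Kelantan replicate 2 (-0.47), Brangus replicate 1 (-0.58) or Holstein Friesian replicate 1 (-0.35). The immediate early median was -0.05 without Brangus replicate 1, and the glycolysis and neutrophil medians were 0.01 and 0.20 without Brangus replicate 2. Adjusted over the list alone, 2 selenoprotein, 2 MHC class I, 2 inflammatory, 1 immediate early and 1 erythroid gene passed. The glycolysis test pointed higher against its median, and the neutrophil, fatty acid oxidation and selenoprotein lists had means of the opposite sign to their medians.

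Tested together, no gene differed between any breeds with edgeR (smallest adjusted p = 0.123), with 1107 at an unadjusted p under 0.05, while DESeq2's likelihood ratio test called 625. The 2 comparisons against Holstein Friesian shared their 1 called gene, LOC539009, where independent lists of this size would share 7.4e-05. In 50 draws, all 6 libraries were simulated without a breed difference, and both comparisons shared the simulated Holstein Friesian libraries. A gene was shared in 3 draws, with a mean of 0.08 and at most 2. Those draws gave a call for Kedah-Kelantan against Holstein Friesian in 14 of 50 and for Brangus against Holstein Friesian in 9 of 50, so the number of calls is within what they gave. The draws used 1 spread per gene for all breeds, although the real breeds differed in spread, and they do not bear on LOC539009 itself. LOC539009 was low in both Holstein Friesian libraries (5 and 9 counts), and this low level led to its call. Fits with only 1 of these libraries are therefore no independent check of it. Without replicate 1 its log2 fold change was 7.00 for Kedah-Kelantan and 6.95 for Brangus, and without replicate 2 it was 7.97 and 7.92. Brangus, which the labels call intermediate in heat tolerance, had a mean between the other breeds for LOC539009 and for 3054 of 13455 tested genes (22.7%), above both for 5013 and below both for 5388. For LOC539009 the Brangus libraries overlapped those of Kedah-Kelantan (43.0 ± 4.14 against 44.5 ± 4.29 CPM). Holstein Friesian was far lower (0.255 ± 0.123 CPM), so Brangus was not midway for this gene.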

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

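Of the alternatives, 3 were chosen after the data were seen, namely the filter at a mean count of 50, the myeloid marker score as a covariate and the removal of a gene length trend. For the lists, the fit of only Kedah-Kelantan and Brangus was added then as well. All other alternatives were set before. Over the values named above and their alternatives other than left-out libraries, 1759 single-gene and list results kept their direction and side of the threshold, 206 newly passed, 19 no longer passed and 14 reversed. Where a result changed, the cause was not tested unless stated.

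Genes called for Kedah-Kelantan against Holstein Friesian numbered 1 in the main test, 131 with DESeq2, 2 with limma-trend on log2(FPKM + 1), and 0 with only the 2 breeds or a mean count of at least 50. For Brangus against Holstein Friesian they numbered 1 in the main test, 313 with DESeq2, and 0 with median-of-ratios size factors, only the 2 breeds or a mean count of at least 50. For Kedah-Kelantan against Brangus they numbered 0 in the main test, 672 with DESeq2 and 2537 with only the 2 breeds. For any breed difference they numbered 0 in the main test, 625 with DESeq2, and 1 without a low-count filter and in each of the 3 limma-trend fits of FPKM. The myeloid score, which differed mostly between the 2 Holstein Friesian libraries, gave 582, 1527, 1998 and 2242 in the same order. The 2537 calls come from a fit whose spread leaves out the Holstein Friesian libraries, which differ most from each other (2003 genes over 2-fold). Fits that left out 1 library gave 0 to 2464, 0 to 4395, 0 to 2458 and 0 to 4783 calls. The count was 0 without any 1 of the Kedah-Kelantan or Brangus libraries and above 0 only without a Holstein Friesian library. A breed left with 1 library was assumed to vary like the others. Genes called in both comparisons against Holstein Friesian numbered 1 in the main test, 0 with median-of-ratios size factors and 34 with DESeq2. Brangus lay between the other breeds for 0 to 1103 called genes when 1 library was left out, where 0 to 2464 were called. With DESeq2, 522 genes had no adjusted p for Kedah-Kelantan against Holstein Friesian.

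The replicate numbers did not pair the samples, since the replicate differences of different breeds correlated at 0, 0.01 and 0.05. With the replicate number as a block, 0 genes were called in each comparison, so the call of LOC539009 was lost, at log2 fold changes of 7.45 for LOC539009, Kedah-Kelantan against Holstein Friesian, and 7.41 for LOC539009, Brangus against Holstein Friesian, against 7.44 and 7.39 in the main test. Under the block HSPA1A, Kedah-Kelantan against Holstein Friesian, was 0.04, reversed.

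Camera at the preset correlation called 10, 10 and 15 lists. With an estimated correlation it called 0, 0 and 0. That version tests on the 3 residual degrees of freedom, which leaves it little power. For Kedah-Kelantan against Brangus, the estimated correlation of cell cycle genes was -0.02, below the preset 0.01. Their camera adjusted p still rose from 1.39e-08 to 0.172, so the lost calls do not measure correlation between genes alone. Fry, which tests whether a list's genes move one way and does not compare them with other genes, called 1, 1 and 2. It called cell cycle genes in each comparison (fry adjusted p = 0.0348, 0.0428 and 0.00565). The second list for Kedah-Kelantan against Brangus was erythroid markers (fry adjusted p = 0.016). Fits that left out 1 library called 5 to 15 lists for Kedah-Kelantan against Holstein Friesian. For Kedah-Kelantan against Brangus, heat shock, both oxidative phosphorylation lists, ribosomal, cell cycle, platelet, NK and eosinophil lists kept their call under each alternative with which camera was run at the preset correlation, as did heat shock, mitochondrially encoded and ribosomal lists for Brangus against Holstein Friesian. No list did so for Kedah-Kelantan against Holstein Friesian.

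Of lists called in the main test, the medians that changed sign when 1 library was left out ranged as follows. For Kedah-Kelantan against Holstein Friesian, the unfolded protein response ranged from -0.26 to 0.04, glycolysis from -0.85 to 0.29, ribosomal proteins from -0.76 to 0.05, gamma delta T cell markers from -1.33 to 0.19 and NK markers from -0.03 to 1.21. For Brangus against Holstein Friesian, interferon-stimulated genes ranged from -1.21 to 0.21, B and plasma cell markers from -0.15 to 3.16 and eosinophil markers from -3.97 to 0.19.

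Single genes ranged likewise. Brangus against Holstein Friesian: deiodinase genes gave DIO2 from -4.74 to -0.82, and Kedah-Kelantan against Brangus: deiodinase genes gave DIO2 from -0.67 to 0.88, apart from the fits without Brangus replicate 2, whose -9.32 and 5.79 were fitted over a Brangus count of 0 and are not measured folds. TARP, Kedah-Kelantan against Holstein Friesian, ranged from -2.76 to 0.84, HSPA1A, Kedah-Kelantan against Holstein Friesian, from -0.39 to 0.47, THRA, Kedah-Kelantan against Holstein Friesian, from -0.08 to 0.56, and THRB, Kedah-Kelantan against Holstein Friesian, from -1.59 to 0.67. HSPA1A, Brangus against Holstein Friesian, ranged from -0.31 to 0.56, and THRA, Brangus against Holstein Friesian, from -0.22 to 0.41. HSF1, Kedah-Kelantan against Brangus, ranged from -0.20 to 0.06.

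The FPKM fits moved the median of all genes to 0.12, 0.18 and 0.07 for Kedah-Kelantan against Holstein Friesian and to 0.19, 0.28 and 0.11 for Kedah-Kelantan against Brangus (pseudocount 1, 0.1, and 1 without a filter). In those fits HSPA1A, Kedah-Kelantan against Holstein Friesian, was 0.22, 0.22 and 0.22, and both HSPA1A, Kedah-Kelantan against Brangus, and HSF1, Kedah-Kelantan against Brangus, were 0.17, 0.18 and 0.17. Their signs changed in fits that raised the median of all genes too, and these changes are among the 14 counted as reversed. Removing the length trend moved these medians to -0.14 and -0.10, and gave -0.10 for THRA, Kedah-Kelantan against Brangus, -0.02 for COX6B1, Brangus against Holstein Friesian, and -0.01 for nuclear-encoded oxidative phosphorylation, Brangus against Holstein Friesian. The myeloid score gave 0.02 for HSPA1A, Kedah-Kelantan against Holstein Friesian. Depth limits DIO1, DIO3 and genes near 3 counts per library.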

Other observations

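The genes in the first 2 paragraphs were chosen after their values were seen, and of the tests in the later paragraphs, those of the cell mix, the wrong label, the animal in place of another, the count filter and the RRAGA copy were chosen only after the result was seen.

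Several immune genes were abundant in some libraries and nearly absent from others, replicate 1 of each breed being given first. IL32, a proinflammatory cytokine gene, had 141 and 181 counts in Kedah-Kelantan, 5204 and 4095 in Brangus, and 0 and 1841 in Holstein Friesian. LOC100336795, described as UL16-binding protein 3, a ligand of the NK receptor encoded by KLRK1, had 0 and 0, 287 and 147, and 140 and 105. Among MHC class II genes, the DQA genes summed to 2214 and 2633, 3 and 5022, and 14426 and 3732 counts, and BOLA-DQB gave 2 and 0, 6 and 6548, and 14514 and 4882. BOLA-DQA2 alone had 2212 and 2628, 0 and 1484, and 2 and 0. The counts of BLA-DQB, another tested gene entry, are not given here, so low BOLA-DQB counts do not show an absence of DQB expression. The class II gene BOLA-DRA had 57144 to 128615 counts in all 6 libraries. The DQ genes are highly polymorphic between animals, and no explanation was tested.

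Eosinophil genes varied likewise, within and between breeds. CCR3, the eotaxin receptor gene, had 4651 and 5203 counts in Kedah-Kelantan, 423 and 522 in Brangus, and 221 and 12643 in Holstein Friesian. GATA2 had 127 and 152, 0 and 0, and 1 and 339, and SMPD3 had 725 and 680, 0 and 11, and 6 and 1562. MS4A1, the B cell antigen CD20 gene, went the other way within Holstein Friesian, with 32371 and 1196 counts against 19836 to 26427 in the other 4 libraries. LOC100848700, described as an ATP-binding cassette sub-family C member 4, had 3871 and 4278, 2448 and 981, and 5 and 8 counts, and LOC617224, a palmitoyltransferase ZDHHC11B gene, had 284 and 264, 86 and 188, and 0 and 0. LOC101903284, a Golgi phosphoprotein 3-like gene, had 0 and 4, 0 and 10, and 154 and 238.

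The 2 Holstein Friesian libraries differed over 2-fold in 22% of 9112 genes. Removing a gene length trend left 100.3% of these differences (1997 before, 2002 after), which argues against length bias. Whether a Kedah-Kelantan or Brangus animal stood in place of one of them could not be decided. In all, 5 genes set both apart from the other 4 libraries, where the 12 mixed pairs of libraries had at most 2. However, LOC539009, LOC100848700 and LOC617224 are among these 5 and had been seen before the test was set, so the count is not independent of that choice. A different mix of blood cells may account for part of the pattern, since 66.2% of 210 cell type markers differed over 2-fold, against 32.0% of genes matched on expression and at most 40.0% in 1000 draws. A wrong label on an animal from outside the study cannot be told apart, since the test was void: of 23 genes picked because replicate 1 stood apart from the other breeds, replicate 2 was on its side for 8.7%, which met the condition for a wrong label, but genes picked on replicate 2 gave a low share too (2 of 41), in a mirrored run that was added after the 8.7% was seen and changed the reading from a wrong label to undecided, the count limit having been lowered earlier, after a first run in which no gene met the stricter one. A difference in health or sampling between the animals behind the 2 Holstein Friesian libraries stays open and untested.

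The Brangus libraries had few genes with low counts, 282 and 149 with 1 to 3 counts against 1088 and 975 in Kedah-Kelantan. A lower total does not account for it, since Kedah-Kelantan libraries thinned to the smallest total had at least 3.63 times as many. A filter by the authors that removed every gene with 1 to 3 counts does not account for it either, since 149 such genes remained in the library with fewer of them. Filters of other kinds were not tested. The most frequent low count was 6 and 12 in the Brangus libraries and 1 in the other 4. Few distinct molecules, amplified, may be the source: of genes with 8 to 15 counts in one library, 37.5% (95% interval 34.9 to 40.2) had 0 in the other Brangus library, against 4.3% (3.3 to 5.4) in Kedah-Kelantan and 21.4% (19.2 to 23.7) in Holstein Friesian, where the replicates also differ in other ways. A breed difference in the blood itself stays open as untested.

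Several gene copies were far lower in both libraries of 1 breed. For LOC539009, reads shared with RRAGA may account for the call, since the higher CPM of RRAGA in Holstein Friesian made up 1.15 times (SE 0.04) the CPM missing from the copy, and the sum was 88.8 ± 0.7 against 82.5 ± 6.5 CPM in the other 4 libraries, although the sequences were not compared here. For LOC101905242 and ANAPC15 the same ratio was -0.08 (SE 1.31), and for LOC789829 and SNX5 it was -1.39 (SE 1.81), both too uncertain to decide. Each SE carries only the spread of RRAGA, ANAPC15 or SNX5 and takes the difference of the copy as exact, so it is too small. A variant carried by the breed that moves reads to the other copy, or a true difference in expression, stays open and untested.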
